A study of Mus musculus with 6 samples.

How the data were processed

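RNA was profiled in 6 mouse samples of Lin-c-Kit+Sca-1+ bone marrow cells, the gate that holds blood stem and early progenitor cells. Per the labels' protocols, donor marrow was transduced with a retrovirus carrying BCR-ABL and GFP or GFP alone and transplanted into B6 recipients. BCR-ABL is the fusion kinase of chronic myeloid leukaemia (CML). GFP-positive cells of the gate were sorted 14 days after transplantation. From 100 to 300 ng of total RNA was amplified, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The samples form 3 groups of 2 arrays, taken from the sample titles. HSC denotes cells of the gate without BCR-ABL, LSC (leukaemia stem cells) the BCR-ABL cells from wild-type donors, and Alox5-/- LSC the BCR-ABL cells from donors lacking Alox5. The titles number the arrays as biological replicates, and no source used here says how many animals contributed to each. P-values therefore measure the spread between these samples.

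The deposited table holds 1 score per probe set and array. Per the submitters' processing notes, the tools were Affymetrix Expression Console 1.1 and RMA, a method that returns log2 expression. The deposited scores do not have the range of log2 expression. They ran from 0 to 62.1, and between 33.5% and 53.7% of the probe sets of an array lay above 16, the most that log2 of a 16-bit scan can reach. Array medians ran from 14.5 to 16.4, so the columns had not been quantile normalized to each other. No source used here names the quantity, its log base or its direction, and a higher deposited score cannot be read as higher expression. Differences are therefore given as differences of the deposited score, with no fold change. Of 35557 probe sets, 1058 were empty on all 6 arrays and 0 on only some of them, and 34499 carried values.

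Gene symbols came from the platform annotation. It gave 1 symbol to 21789 probe sets and several to 1621, and 12147 were not listed in it. Of the probe sets with 1 symbol, 21698 were matched by Entrez identifier to RefSeq genes of assembly GRCm38.p6, and 0 symbols were updated. Positions in that assembly served only to find the neighbours of Alox5, since no build is named for the array. Probe sets with several symbols were not used for genes. Where a symbol had several probe sets, the 1 with the highest mean over all 6 arrays was kept, which left 19934 genes.

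Each gene was tested with limma 3.58.1 in R 4.3.3, on the deposited scores, with a mean per group and a spread shared over all 6 arrays. The fit left 3 residual degrees of freedom, and the empirical Bayes step allowed the prior variance to follow the mean score. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 19934 genes, and the threshold was 0.05. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That design assumed log2 expression and left out probe sets below the 25th percentile as dim. A low score is not known to mark a dim probe set, so all genes were tested and that filter became an alternative. This change was made before any call was seen. The same tests were checked on simulated data made from the real means and the spread of each gene after the empirical Bayes step. In each run 200 genes were shifted, 50 each by 4, 8, 16 and 24 units. Of genes shifted by 4 units, 3.33% were called for LSC versus HSC, 2.67% for Alox5-/- LSC versus LSC and 2.67% for Alox5-/- LSC versus HSC. For a shift of 8 units the shares were 50%, 44.7% and 56%, and for 16 units they were 100% in each. The Benjamini-Hochberg method is more lenient when many genes have a small p. These shares therefore hold for runs with many large shifts and may be lower in data without them. False calls made up 6.86%, 4.38% and 7.84% of the calls. The precision is limited by the number of arrays.

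Gene lists numbered 41, and 38 of them were tested as sets. Each needed at least 5 measured members. Sets were tested with camera in limma at a preset correlation of 0.01, adjusted over 114 list tests. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with all other genes, so list medians are given relative to the median of all genes. Genes of the gate (Kit, Ly6a), of the construct (Bcr, Abl1) and of other stem and progenitor surface markers (Ptprc, Cd34, Slamf1, Cd48, Flt3), genes followed by the same laboratory and sex-linked genes were read gene by gene.

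The rule for named genes took Alox5, Kit, Ly6a, Bcr, Abl1, Msr1, Blk, Scd1, Hif1a and Ctnnb1 in every comparison, and an item that is not reported here. It added up to 8 genes past the threshold with the largest differences in each direction, leaving out unnamed gene models. Where fewer than 5 genes passed in all, it took the 5 genes with the smallest p in each direction, as values and not as changes. It also took past-threshold members of passing lists and genes past the threshold in opposite directions in both comparisons that hold the LSC arrays. No gene or list passed, so these last parts named none. Ly6a was not analysed here under a single symbol.

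Alternatives covered the filter, the variance trend, the rule for choosing a probe set, quantile normalization, centring of arrays, array weights, a log2(score + 1) scale and a fit to the 4 arrays compared. They also covered a replicate block, the number that ends each sample's description as a covariate, and each array left out in turn. Figures and class comparisons used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and permutation tests drew 100000 resamples.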

Results

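The data comprised 6 whole-transcript arrays of sorted mouse Lin-c-Kit+Sca-1+ bone marrow cells, with 2 arrays in each of 3 groups. HSC carried the GFP vector, LSC carried BCR-ABL in wild-type cells, and Alox5-/- LSC carried BCR-ABL in cells from donors lacking Alox5, the gene of arachidonate 5-lipoxygenase. A vector group from Alox5-/- donors was not analysed here, so the effect of Alox5 without BCR-ABL was not compared. Every mean and SD of a group rests on n = 2. The unit of the deposited values is not stated, and a higher value cannot be read as higher expression. Array medians were 15.6 and 16.4 for HSC, 15.5 and 15.5 for LSC, and 15.7 and 14.5 for Alox5-/- LSC. Across probe sets, which are not independent replicates, the 3 pairs of arrays of the same group correlated at 0.794 to 0.824 (Pearson). The 12 pairs from different groups correlated at 0.782 to 0.839. The first principal component held 33.7% of the variance and set HSC replicate 2 (coordinate 262) opposite Alox5-/- LSC replicate 2 (coordinate -217). The second held 22.2% and set Alox5-/- LSC replicate 1 (coordinate 255) apart, so neither component separated the 3 groups.

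**Figure D1:**
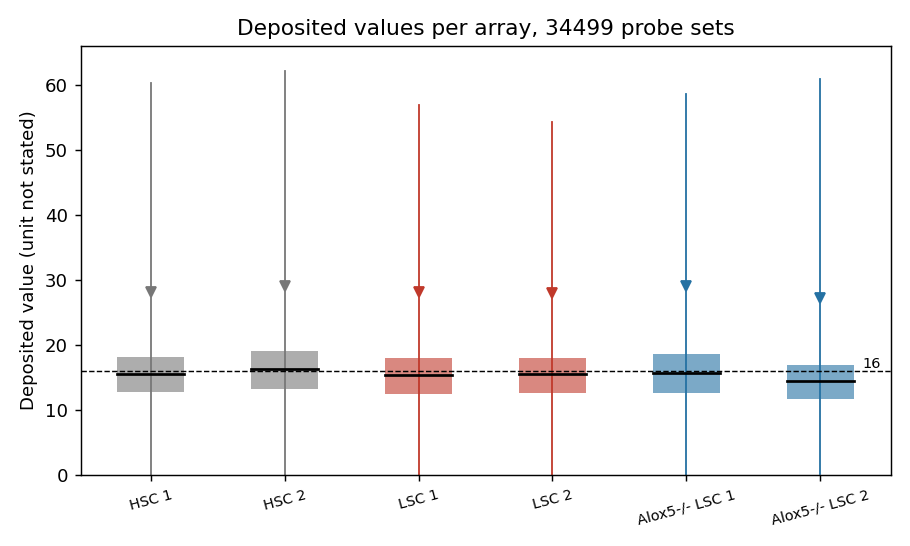
Deposited values of each array (vertical axis, unit not stated) for the 34499 probe sets with values; boxes span the quartiles, black lines mark medians, triangles the 99th percentile and thin lines the full range. Every array passed the dashed line at 16, the top of a 16-bit log2 scale, and the lowest median, 14.5, belonged to Alox5-/- LSC replicate 2.

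Alox5, the gene missing from the donors of 1 group, was read first. Its values were 12.6 and 19.9 on the HSC arrays, 13.2 and 14.2 on the LSC arrays, and 14.4 and 13.5 on the Alox5-/- LSC arrays. Alox5-/- LSC minus LSC was 0.26 ± 2.23 (SE; limma adjusted p = 1.00), within the spread between replicates. A whole-transcript probe set can hold probes outside the disrupted part of the gene, and the direction of the values is unknown. The Alox5 value therefore checks neither the genotype nor its label.

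The first comparison, LSC against HSC, addressed which genes BCR-ABL regulates in these cells. The genes with the smallest p had higher values in LSCs for Vps72, a subunit of complexes that deposit the histone variant H2A.Z, and for Kynu, a kynureninase of tryptophan breakdown. Vps72 stood at 16.94 ± 0.58 (SD) in LSCs and 8.63 ± 0.20 in HSCs, and Kynu at 24.3 ± 2.15 and 15.1 ± 0.29. Values were lower in LSCs for Rnf5, a ubiquitin ligase of the endoplasmic reticulum (8.90 ± 0.30 against 17.86 ± 0.39), and for Crtc2, a coactivator of CREB (14.3 ± 0.36 against 22.6 ± 0.25). None of these differences passed correction over all genes.

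Among the other genes with the smallest p, LSC minus HSC was 8.40 for Vpreb3, which takes part in assembly of the pre-B cell receptor. It was 7.03 for Bbs7, a component of the ciliary BBSome, and 6.74 for Hp, haptoglobin. Differences of -12.29 for Cyb5b, a mitochondrial cytochrome b5, -7.89 for Ddias and -7.97 for Rtn4ip1, a mitochondrial oxidoreductase, ran the other way. Unadjusted limma p for these 10 genes ran from 7.89e-05 for Rnf5 to 0.00108 for Hp, and their smallest adjusted p was 0.722. Genes named in every comparison had p above 0.09. Ctnnb1, beta-catenin, differed by -3.07 ± 1.57 (SE), Msr1, a scavenger receptor, by -2.53 ± 2.40, and Kit by -1.18 ± 1.53. Scd1, a fatty acid desaturase, differed by -0.82, Bcr by 0.63 and Abl1 by 0.28. Blk, a Src family kinase, differed by -0.52 and by 0.03 after centring, and Hif1a by -0.13 and by 0.42 after centring and 0.37 after quantile normalization. Alox5 differed by -2.54, and by 1.1 without HSC replicate 2. Msr1 ran from -3.99 without HSC replicate 1 to -1.07 without HSC replicate 2. Leaving out 1 array also changed the sign of other small differences. Kit was 0.22 without HSC replicate 2 and 0.51 without LSC replicate 1, and Bcr was -0.25 without HSC replicate 1 and -0.50 without LSC replicate 1. Abl1 was -0.12 without HSC replicate 2, and Scd1 was 1.38 without LSC replicate 2. Over leave-one-out fits Blk ran from -1.87 to 0.83, changing sign without HSC replicate 2 and without LSC replicate 2, and Hif1a from -0.57 to 0.31, changing sign without LSC replicate 2.

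No gene passed in LSC against HSC by limma, with 0 of 19934 genes at an adjusted p under 0.05 and 0 under 0.1. At an unadjusted p under 0.05 there were 939 genes, where chance gives 996.7, of which 193 had higher and 746 lower values in LSCs. The median difference over all genes was -0.47. Among genes with p under 0.05, chosen anew in each setting, 79.4% had lower values as deposited. The share was 57.3% of 1062 genes after quantile normalization and 57.2% of 1024 genes after centring. The count was 1566 without HSC replicate 1 and 602 without LSC replicate 1. The groups did not overlap for 34.2% of genes, against 33.3% by chance for 2 arrays against 2.

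**Figure D2:**
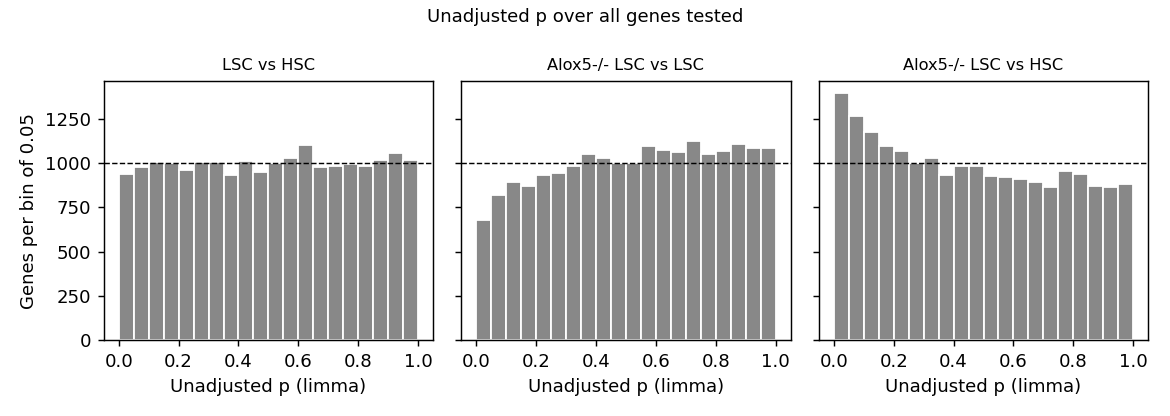
Number of genes (vertical axis) in bins of 0.05 of the unadjusted limma p (horizontal axis) for the 3 comparisons; the dashed line marks the 996.7 genes per bin that chance gives. The first bin held 939 genes for LSC against HSC, 678 for Alox5-/- LSC against LSC and 1392 for Alox5-/- LSC against HSC.

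Gene lists were read as medians of LSC minus HSC relative to the median of all genes. Of 705 genes in the tested lists, 52 had an unadjusted limma p under 0.05 in LSC against HSC (13 higher and 39 lower). In Alox5-/- LSC against LSC there were 27 (7 and 20), and in Alox5-/- LSC against HSC 64 (13 and 51). Over all genes tested, the shares at that p were 4.71%, 3.40% and 6.98% in the same order. Part of these list members are named, chosen after their values were seen, with differences as deposited. Cytosolic ribosomal protein genes had the smallest camera p, with lower values in LSCs, a relative median of -1.16 and 22 of 23 members below 0 as deposited, among them Rps9 at -3.29. Camera gave p = 0.00182 and an adjusted p of 0.104, and p = 0.240 with an estimated correlation. The adjusted p was 0.00398 without HSC replicate 2, 0.0278 without LSC replicate 2, 0.925 without HSC replicate 1 and 0.842 with the probe set of lowest mean per gene. S phase genes had a relative median of -0.76 (camera adjusted p = 0.505; p = 0.401 with an estimated correlation), and 3 of 29 members had lower values at p under 0.05. These were Mcm2 (-4.00), a subunit of the replicative helicase, Prim1 (-6.26), a primase, and Rfc3 (-4.97), part of the clamp loader. Without LSC replicate 2 the S phase list passed at an adjusted p of 0.0313. G2 and M phase genes had a relative median of -0.57 (camera adjusted p = 0.619; p = 0.452 with an estimated correlation), with Ccna2 (-4.36), Cdca8 (-5.34) and Aurka (-3.73) lower at p under 0.05. Glycolysis genes had a relative median of -1.15 (camera adjusted p = 0.619), and 4 of 17 members were lower at p under 0.05, among them the glucose transporter Slc2a1 at -5.28 and Pgk1 at -3.32. None of the 114 list tests over the 3 comparisons passed with camera, with an estimated correlation or with fry.

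Lists of cell identity did not pass either in LSC against HSC. Long-term HSC genes had a relative median of 0.43 (camera adjusted p = 0.816), with Slamf1 (5.31) and Procr (3.69) higher and Angpt1 (-7.06) and Meis1 (-4.52) lower in LSCs at p under 0.05. Lymphoid priming genes had 0.77 (adjusted p = 0.904), with Dntt at 6.90, Irf8 at -4.87 and Cd34 at -3.43. Granulocyte and neutrophil progenitor genes had -0.13 (adjusted p = 0.954), with Csf3r at -4.11 and Fcnb at -3.18. Mast cell, basophil and eosinophil genes had 0.72 (adjusted p = 0.918), with Cpa3 at -5.76 and Mcpt8 at -6.61. Megakaryocyte and platelet genes had -1.06 (adjusted p = 0.945), T and NK cell genes -0.39 (adjusted p = 0.918), dendritic cell genes 0.30 (adjusted p = 0.908) and stromal and endothelial genes 0.58 (adjusted p = 0.816). Monocyte and macrophage genes had -0.36 (adjusted p = 0.904), with Mrc1 at 7.44, C1qb at -6.92 and Cx3cr1 at -6.59, erythroid genes -0.19 (adjusted p = 0.945) and B cell genes 0.07 (adjusted p = 0.945), with Vpreb1 at -4.35.

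Adjustment over the list alone was made in each of the 38 lists without correction over lists, so some may hold a call by chance. So adjusted, 5 members in 3 lists passed in LSC against HSC, and 0 passed over all genes. They were the B cell receptor chain Cd79a (-10.60) and Vpreb3 (8.40), the complement chain C1qb (-6.92) and the chemokine receptor Cx3cr1 (-6.59) of the macrophage list, and Rhag (11.03) of the erythroid list. In a list of gate genes, construct genes and other stem and progenitor surface markers, 2 of 8 measured genes had p under 0.05. Both were markers outside the sorting gate, Slamf1 (5.31), which passed when adjusted over the list alone, and Cd34 (-3.43). Of the genes followed by the same laboratory and the sex-linked genes, 0 had p under 0.05 in any comparison. The first of these lists was chosen for what the group studied and is not independent evidence.

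Signalling, metabolic and stress lists were likewise below threshold in LSC against HSC. STAT5 target genes had a relative median of 0.02 (camera adjusted p = 0.966), with the STAT5-induced feedback gene Socs2 at 7.83 and the cyclin Ccnd2 at -2.98. MAPK feedback genes had -0.65 (adjusted p = 0.954), FoxO target genes -0.07 (adjusted p = 0.966; Foxo1 at -5.06, Txnip at -3.11 and Trib1 at 4.67), Wnt and beta-catenin genes -0.42 (adjusted p = 0.945) and Hedgehog genes -0.12 (adjusted p = 0.980). Leukotriene and eicosanoid genes, the pathway of Alox5, had 0.32 (adjusted p = 0.955), with the leukotriene B4 receptor Ltb4r1 at -4.49 and the prostacyclin receptor Ptgir at -3.95. Hypoxia response genes had -0.20 (adjusted p = 0.904), with Bnip3 at -6.91, oxidative phosphorylation genes -0.41 (adjusted p = 0.619), cholesterol and fatty acid synthesis genes 0.25 (adjusted p = 0.908) and antioxidant response genes 0.66 (adjusted p = 0.816). Interferon response genes had -0.39 (adjusted p = 0.954), with Rtp4 at 6.31, Ddx58 at 3.56 and Mx1 at -7.37. Inflammatory and NF-kappaB genes had 0.55 (adjusted p = 0.908), antigen presentation genes 0.39 (adjusted p = 0.945), BCL2 family genes -0.47 (adjusted p = 0.945) and p53 target genes -0.08 (adjusted p = 0.954). Cell cycle inhibitors had 0.24 (adjusted p = 0.908), adhesion and homing genes 0.18 (adjusted p = 0.958), ribosome biogenesis genes -0.96 (adjusted p = 0.619) and unfolded protein response genes 0.50 (adjusted p = 0.904). Ribosome biogenesis genes passed at an adjusted p of 0.0278 without LSC replicate 2, while camera over all arrays gave p = 0.479 with an estimated correlation. Their members Ddx21 (-4.86) and Npm1 (-3.12) were lower at p under 0.05. DNA repair genes had -0.35 (adjusted p = 0.945), Src family kinases 0.41 (adjusted p = 0.954), TGF-beta target genes -0.28 (adjusted p = 0.816; Tgfbr2 at -5.09) and handling stress genes -0.33 (adjusted p = 0.945). The median difference as deposited, the mean difference and the camera direction differed in sign in 15 of the 38 lists. They differed in 16 for Alox5-/- LSC against LSC and in 23 for Alox5-/- LSC against HSC. Camera is relative to all other genes, whose median difference was negative, so these counts hold that baseline. In LSC against HSC the camera direction was also up for monocyte, interferon response, erythroid, Hedgehog and p53 target genes despite negative relative medians. It was down for B cell genes and for adhesion and homing genes despite positive ones.

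The second comparison, Alox5-/- LSC against LSC, addressed what the absence of Alox5 altered in BCR-ABL cells. The genes with the smallest p had lower values in Alox5-/- LSCs for Vps72 (8.81 ± 1.5 against 16.94 ± 0.58, SD) and Kynu (16.4 ± 0.36 against 24.3 ± 2.15). Values were higher in Alox5-/- LSCs for Rnf5 (14.7 ± 1.14 against 8.90 ± 0.30) and for Mlf1, myeloid leukaemia factor 1 (22.6 ± 2.52 against 14.4 ± 0.07). For Vps72, Kynu and Rnf5 the sign was opposite to that of LSC minus HSC. None of these differences passed correction over all genes.

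**Figure D3:**
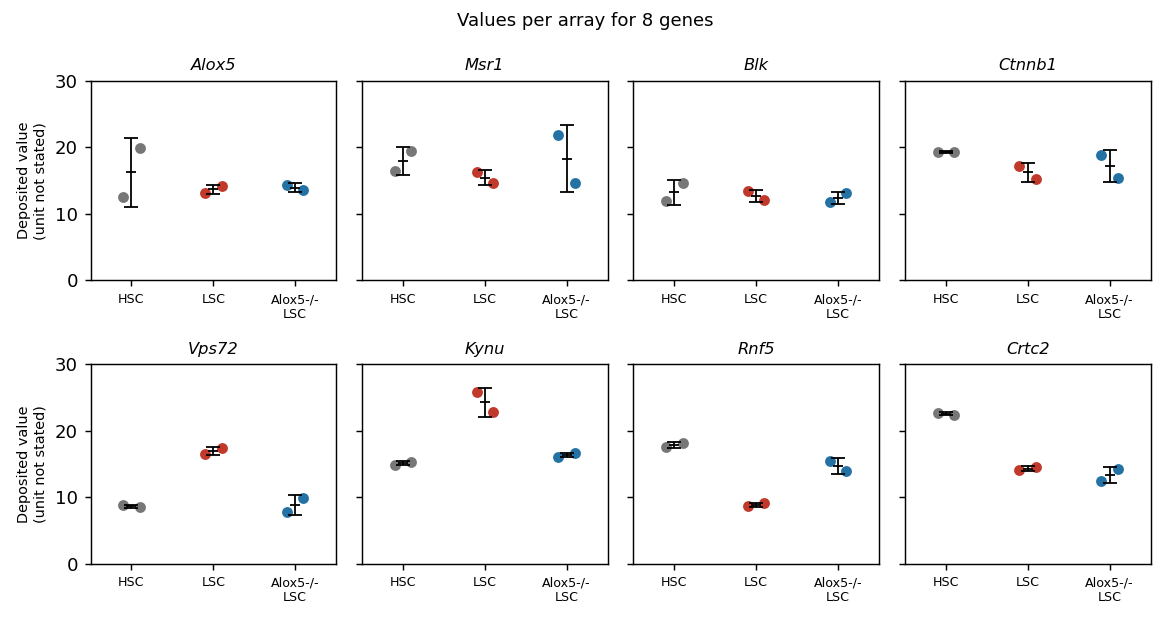
Deposited values per array (vertical axis, unit not stated) for 8 named genes in the 3 groups; points are arrays, and the black marks are the mean and SD of 2 arrays. Alox5 ran from 12.6 to 19.9 within HSC alone, and Vps72 lay at 16.9 on average in LSC against 8.63 in HSC and 8.81 in Alox5-/- LSC.

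Among the other genes with the smallest p, Alox5-/- LSC minus LSC was 7.01 for the zinc finger gene Zfp420, 5.71 for Cabcoco1 and 6.15 for Mmgt1, a subunit of the endoplasmic reticulum membrane complex. It was -9.83 for the interferon-inducible Samd9l, -8.07 for Mvd, a decarboxylase of the mevalonate pathway, and -6.12 for Zmpste24, the protease that matures prelamin A. Zmpste24 differed by 0.02 with its probe set of lowest mean. Unadjusted limma p for these 10 genes ran from 0.000145 for Vps72 to 0.00264 for Mmgt1, and each adjusted p was 1.00. Genes named in every comparison had p above 0.26, with Msr1 at 2.86 ± 2.40 (SE), Kit at -1.81 ± 1.53 and Abl1 at 1.54 ± 1.26. Hif1a differed by 0.53 and Bcr by -0.48. Ctnnb1 differed by 0.94 and by -1.1 with the description number as a covariate. Blk differed by -0.27, by 0.07 after centring and 0.23 after quantile normalization. With the description number as a covariate Blk also changed sign, by more than under either scaling. Scd1 differed by -0.19, by 0.15 after centring and 0.36 after quantile normalization. Msr1 rested on 1 array: it stood at 21.9 and 14.7 on the Alox5-/- LSC arrays and differed by -0.74 without Alox5-/- LSC replicate 1. Kit ran from -3.5 without LSC replicate 1 to -0.12 without LSC replicate 2, Abl1 from 0.29 without Alox5-/- LSC replicate 1 to 2.79 without replicate 2 of that group, and Hif1a from 0.09 without LSC replicate 2 to 0.97 without LSC replicate 1. Leave-one-out values also changed sign for Bcr (-1.61 to 0.66, without LSC replicate 1), and for Scd1 (-2.39 to 2.01), Blk (-0.93 to 0.39) and Alox5 (-0.24 to 0.76) without LSC replicate 1 and without Alox5-/- LSC replicate 1. Ctnnb1 (-0.79 to 2.67) changed sign without LSC replicate 2 and without Alox5-/- LSC replicate 1.

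In Alox5-/- LSC against LSC, limma called 0 of 19934 genes at an adjusted p under 0.05 and 0 under 0.1. At an unadjusted p under 0.05 there were 678 genes, where chance gives 996.7, of which 162 had higher and 516 lower values in Alox5-/- LSCs. The median difference over all genes was -0.30. Among genes with p under 0.05, chosen anew in each setting, 76.1% had lower values as deposited. The share was 54.0% after quantile normalization and 52.5% after centring. Without Alox5-/- LSC replicate 2 the count was 1307 and the share 22.5%. The groups did not overlap for 30.6% of genes, against 33.3% by chance.

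Cytosolic ribosomal protein genes had a median of 0.94 relative to all genes in Alox5-/- LSC minus LSC, with 17 of 23 members above 0. Camera gave p = 0.000858 and an adjusted p of 0.0979, and p = 0.216 with an estimated correlation. The adjusted p was 0.0363 without HSC replicate 2, 0.0243 without LSC replicate 2, 0.688 without LSC replicate 1 and 0.897 with the probe set of lowest mean. BCL2 family genes had a relative median of 1.59 (camera adjusted p = 0.505; p = 0.0837 with an estimated correlation), with 10 of 14 members above 0 and the survival gene Bcl2l1 at -4.91, lower at p under 0.05. Handling stress genes had 0.58 (camera adjusted p = 0.505; p = 0.236 with an estimated correlation) and glycolysis genes 0.66 (adjusted p = 0.619; p = 0.308 with an estimated correlation). S phase genes had 0.91 (adjusted p = 0.619) and G2 and M phase genes 0.03 (adjusted p = 0.966). Leukotriene and eicosanoid genes had 0.38 (adjusted p = 0.945), and 0 of 26 members had p under 0.05. Interferon response genes had -1.06 (adjusted p = 0.816), with Rtp4 (-5.28), Ifih1 (-4.92) and Ddx58 (-4.12) lower at p under 0.05. Long-term HSC genes had -0.36 (adjusted p = 0.816), with Esam at 5.35 and Ctnnal1 at -8.36. Adjusted over the list alone, with no correction over lists, 2 members passed in this comparison and 0 passed over all genes. These were Mvd (-8.07) of the cholesterol and fatty acid list and Rag2 (-10.21), a recombinase subunit of the lymphoid priming list. Cholesterol genes otherwise ran both ways, with Idi1 at 14.23, Fdft1 at 6.30 and Acly at -4.69.

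The third comparison, Alox5-/- LSC against HSC, differed in both BCR-ABL and Alox5. The genes with the smallest p had lower values in Alox5-/- LSCs for Ube2h, a ubiquitin-conjugating enzyme (15.1 ± 1.04 against 28.5 ± 0.23, SD), and for Nae1, a subunit of the NEDD8-activating enzyme (10.8 ± 0.55 against 21.9 ± 0.23). Rtn4ip1 (-9.28), Crtc2 (-9.23) and Zswim7 (-8.88), a gene of homologous recombination, were also lower. Values were higher for Mettl18, a histidine methyltransferase (11.74), Akr1c6, a steroid dehydrogenase (8.34), Vpreb3 (7.18), Prkce, protein kinase C epsilon (6.15), and Cabcoco1 (5.92). None of these differences passed correction over all genes.

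In this comparison limma called 0 of 19934 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.498. At an unadjusted p under 0.05 there were 1392 genes, where chance gives 996.7, of which 148 had higher and 1244 lower values in Alox5-/- LSCs. The median difference over all genes was -0.78. Among genes with p under 0.05, chosen anew in each setting, 89.4% had lower values as deposited. The share was 55.8% after quantile normalization and 55.0% after centring. Without HSC replicate 2 the count was 804, and without Alox5-/- LSC replicate 2 the share was 42.5%. The groups did not overlap for 35.4% of genes, against 33.3% by chance. Among genes named in every comparison the smallest p was that of Kit, which differed by -2.99 ± 1.53 (SE; limma adjusted p = 0.740), by -4.39 without HSC replicate 1 and by -1.59 without HSC replicate 2.

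Of the lists in Alox5-/- LSC against HSC, antigen presentation genes had the smallest camera p, 0.0450 (adjusted p = 0.619; p = 0.291 with an estimated correlation), with a relative median of 1.33. Monocyte and macrophage genes had 1.11 (adjusted p = 0.619), G2 and M phase genes -0.74 (adjusted p = 0.619), ribosome biogenesis genes -0.75 (adjusted p = 0.619) and ribosomal protein genes 0.01 (adjusted p = 0.966). Adjusted over the list alone, with no correction over lists, 5 members passed and 0 passed over all genes. They were Cd79a (-12.65), Cd72 (-7.13) and Vpreb3 (7.18) of the B cell list, the mitotic kinase Aurka (-7.25), and Ddx21 (-6.22), a nucleolar helicase. Of the long-term HSC list, Procr (4.99), Slamf1 (3.44) and Esam (5.07) were higher and Meis1 (-6.63) and Angpt1 (-8.35) lower in Alox5-/- LSCs at p under 0.05.

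Both LSC minus HSC and Alox5-/- LSC minus LSC hold the LSC arrays with opposite signs, so a negative relation across genes arises with no effect. Vps72, Kynu, Rnf5, Mlf1, Mvd, Samd9l and Zfp420 had p under 0.05 with opposite signs in both, as did 125 genes in all, against 4 with the same sign. No gene was called in both. In 100 simulated draws of unchanged groups that share those arrays, with the residual variance of each gene, the count in opposite directions was 317.5 on average and ran from 269 to 361. With moderated variances it was 234.1, from 188 to 268, and the 125 observed lay below every draw of both simulations. The draws also held more genes with p under 0.05 in the comparisons themselves, on average 1095.8 and 1093.9 with residual variances and 982.1 and 984.8 with moderated variances, against 939 and 678 observed. The lower count of opposite signs was not separated from these lower totals. Both simulations gave the LSC arrays a spread estimated over all 3 groups. The 2 LSC arrays correlated at 0.824 over all probe sets, against 0.794 for HSC and 0.810 for Alox5-/- LSC. If they vary less than the other arrays, the draws hold too many opposite signs and too negative a covariance. The covariance across genes was -1.32 (r = -0.418), against -1.90 (r = -0.500) in the draws with residual variances and -1.41 in those with moderated variances. The observed minus the simulated covariance was 0.582 and 0.093, so the relation was no more negative than in the draws. The draws cannot tell how it compares with shared arrays alone, since they did not use the spread of the LSC arrays alone. With a single LSC array in each difference the covariance was 0.290 or -0.101, depending on the array. That split removes the shared arrays, and a covariance near -1.32 was seen only with them. Each difference in the split rests on a single LSC array, since the group could not be split into parts of 2.

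Genes near Alox5 were compared with all others in Alox5-/- LSC against LSC, since DNA of another strain can remain around a disrupted gene. Within 10 Mb in the GRCm38.p6 annotation, 0 of 202 genes had p under 0.01, against 105 of 19646 elsewhere (two-sided Fisher's exact test, p = 0.630). At the share elsewhere, 0.53%, few of 202 genes would pass, so this test could show only a large excess. At p under 0.05 there were 6 of 202 genes near Alox5 and 668 of 19646 elsewhere.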

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

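Alternatives chosen after the data were seen were the log2(score + 1) scale, the probe set with the lowest mean, every alternative for the counts at an unadjusted p under 0.05 and the share with lower values, the quantile normalization and probe set rules for lists and covariance, and the simulated counts and moderated variances of the covariance. These counts and this share were not named in the design fixed beforehand. Under every setting run, limma called 0 genes in each of the 3 comparisons. The lowest of their smallest adjusted p-values was 0.118, without Alox5-/- LSC replicate 2. Where a group was left with a single array, that array was assumed to vary like the other groups.

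Under the filter at the median, counts at an unadjusted p under 0.05 were 518 for LSC against HSC and 377 for Alox5-/- LSC against LSC. For Alox5-/- LSC against HSC the count was 766. That filter tested 12002 genes against 19934 in the main fit, which by itself lowers the counts. Leave-one-out counts ran from 602 to 1566, 554 to 1307 and 804 to 2031. The leave-one-out share with lower values ran from 64.8% to 88.1%, 22.5% to 92.5% and 42.5% to 95.9%. The number of passing lists ran from 0 to 4 in leave-one-out fits and was 0 in the others. It was 2 without HSC replicate 2 (ribosomal protein genes in both comparisons that hold the LSC arrays) and 4 without LSC replicate 2. The 4 were the same list in both comparisons (adjusted p = 0.0278 and 0.0243), S phase genes (0.0313) and ribosome biogenesis genes (0.0278), both for LSC against HSC. Over all arrays camera with an estimated correlation gave these lists p = 0.240 and 0.216, 0.401 and 0.479. The ribosomal protein list had adjusted p from 0.00398 to 0.925 for LSC against HSC and from 0.0243 to 0.688 for Alox5-/- LSC against LSC over leave-one-out fits. With the probe set of lowest mean it had 0.842 and 0.897, and with probe sets averaged 0.223 and 0.379. The cause of the changes in leave-one-out fits and in lists was not tested.

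Named genes had 867 values under alternatives over 50 gene comparisons, of which 836 kept their direction, 31 changed sign and 0 passed the threshold. Most of these comparisons were of genes picked for the smallest p in these same arrays, whose large differences make a kept sign likely. Of the genes named in every comparison, only Alox5 and Kit were counted for Alox5-/- LSC against HSC. In LSC against HSC, Blk was 0.03 after centring, and Hif1a was 0.37 after quantile normalization and 0.42 after centring. In Alox5-/- LSC against LSC, Blk was 0.23 after quantile normalization, 0.07 after centring and 1.19 with the description number as a covariate. Scd1 was 0.36 and 0.15 under the same 2 scalings, Ctnnb1 was -1.1 with the description number, and Zmpste24 was 0.02 with its probe set of lowest mean. Leave-one-out values in LSC against HSC ran from -6.18 to 1.1 for Alox5, -2.87 to 0.51 for Kit, -0.50 to 1.77 for Bcr, -0.12 to 0.68 for Abl1, -1.87 to 0.83 for Blk, -3.01 to 1.38 for Scd1 and -0.57 to 0.31 for Hif1a. In Alox5-/- LSC against LSC they ran from -0.24 to 0.76 for Alox5, -1.61 to 0.66 for Bcr, -0.74 to 6.45 for Msr1, -0.93 to 0.39 for Blk, -2.39 to 2.01 for Scd1 and -0.79 to 2.67 for Ctnnb1. In Alox5-/- LSC against HSC, Alox5 ran from -5.92 to 1.36. The cause was not tested.

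The observed minus simulated covariance, 0.582, was 0.617 with the 25th percentile filter, 0.233 after quantile normalization and 0.093 against a simulation with moderated variances. The simulated part of each took a spread over all groups, not that of the LSC arrays alone. With a single LSC array in each difference, which removes the shared arrays, the covariance was 0.290 and -0.101. Fisher's test for neighbours of Alox5 gave p of 0.268 to 1 in the other windows and thresholds.

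Arrays with the same replicate number showed no common deviation: their deviations correlated at 0.00017, -0.063 and -0.060 between groups. These values cannot tell whether such arrays were prepared together, which no source used here states. With a replicate block, 0 genes and 0 lists were called, counts at an unadjusted p under 0.05 were 793, 581 and 1160, and the covariance difference was 0.766. Signal over background was not used as a limit, since no source used here names the deposited quantity.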

Other observations

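The tests of wrong identifiers, empty cells, the whole-array difference and co-variation were chosen only after the result was seen, as were the comparisons over all probe sets, over genes with 1 probe set and under other probe set rules. The tests of abundant against silent gene families and of array pairings were fixed before their results were seen, but the wording of the first pattern was changed afterwards. No biological explanation was tested for any pattern. Over all 34499 probe sets, including 12898 without a single gene symbol, limma called 0 in each comparison, with 1704, 1365 and 2223 at an unadjusted p under 0.05.

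The deposited values passed the top of a 16-bit log2 scale, and families of abundant genes went both ways in them. With the probe set of highest mean per gene, glycolysis genes had a median of 18.1 and ribosomal protein genes of the list 17.9. Both lay above the 16.3 of all genes, while proteasome genes at 13.6 and oxidative phosphorylation genes at 15.25 lay below. Over all probe sets, those of ribosomal protein genes had a median of 11.3, against 16.1 for all probe sets with 1 symbol. Chaperonin, hnRNP and elongation factor genes had a median of 15.7 (38 genes), against 16.4 for beta-defensin, keratin-associated and taste receptor genes (118 genes), families taken as silent in blood cells. The difference of -0.70 (bootstrap 95% interval -2.45 to 1.68) lies below the excess of at least 2 that log2 expression was predicted to show, which argues against plain RMA expression values. Identifiers attached to the wrong rows throughout would make ribosomal protein and olfactory receptor probe sets alike. These differed by -4.82 (173 and 1034 probe sets, permutation p = 1e-05, the smallest the resamples can give). Most of these ribosomal protein genes had several probe sets, which are not independent. Among genes with 1 probe set the difference was 0.92 (permutation p = 0.289). Identifiers wrong in part of the rows therefore stay open. A detection filter per array would leave probe sets empty on part of the arrays, of which there were 0. A measure of spread or error across the probes of a probe set may be what was deposited, and this stays open. The families differed in the predicted direction with a permutation p of 0.377, and of 0.270 over all probe sets. The ribosomal difference of -4.82 lay in that direction too, but it was not the comparison predicted. Its sign depended on the probe set rule.

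The ribosomal difference itself depended on how a gene's probe sets were treated. For the same 55 ribosomal protein genes against 1026 olfactory receptor genes it was 2.53 with the probe set of highest mean per gene, -2.83 with the average and -9.87 with the lowest mean (permutation p = 1e-05 in each, the smallest the resamples can give). For the 23 genes of the ribosomal protein list it was 1.75 with the highest mean (permutation p = 0.0338), -5.65 with the average and -9.84 with the lowest. Of the 55 ribosomal protein genes, 20 had 1 probe set, and against 1018 olfactory receptor genes with 1 probe set they differed by 0.92 (permutation p = 0.289). The other 35 had several probe sets, against 8 of 1026 olfactory receptor genes.

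Most genes with p under 0.05 had lower values in Alox5-/- LSCs than in HSCs, 89.4% of 1392. After quantile normalization the share was 55.8% of the 1183 genes with p under 0.05 in that setting. But this setting makes the arrays alike in level and left 57.3% and 54.0% in the other comparisons. Its outcome therefore does not bear on the origin of the imbalance. A whole-array difference in level and a change in the cells cannot be told apart from these values. Without Alox5-/- LSC replicate 2, the array with the lowest median, the share was 42.5%. No source used here gives a batch.

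Ribosomal protein genes as a list lay toward lower values in LSCs than in HSCs and toward higher values in Alox5-/- LSCs than in LSCs, with neither shift past the adjusted threshold. With the correlation between members estimated from the arrays (0.207), the smaller p of both comparisons was 0.216, so co-variation of these genes from array to array may account for the small preset-correlation p-values. Both comparisons share the LSC arrays, and the adjusted p without LSC replicate 1 was 0.688 in each. An effect of BCR-ABL or Alox5 on these genes was not excluded and stays untested beyond these values.

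Arrays of the same group had a mean correlation of 0.728 over the tested genes. Of the 15 ways to pair the 6 arrays, 6 gave a mean as high, the real one included, and the highest other was 0.740. With 15 pairings the share cannot fall under 0.067.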
